A study of Mus musculus with 3 samples.

How the data were processed

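Single-cell RNA sequencing was run on sorted liver non-parenchymal cells of Ai14 (LSL-Tomato) mice, a strain that switches on a red fluorescent protein after Cre recombination. Cells were taken 3 h after injection of PBS, of 20a-LNP or of 20mix-LNP, which are lipid nanoparticles (LNPs) given at 0.3 mg/kg of mRNA. Each of the 3 treatments has 1 library, made with droplet 3' chemistry (10x Genomics, version 3) after enzymatic digestion, red cell lysis and flow sorting, per the labels' protocols. The populations collected in the sort are not given in the sources used here.

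The authors deposited 1 matrix of raw UMI counts for 31053 genes and 4638 cell barcodes, made with Cell Ranger (software version 3.1.0 per the file headers) against mm10. Cell Ranger, STAR, Seurat and edgeR are named in the submitters' processing notes, without versions or roles. The barcodes carry the suffixes 1, 2 and 3, with 1211, 1701 and 1726 barcodes, next to about 2000 cells loaded per treatment per the labels. Whether reads were equalised between libraries on merging is not given in the sources used here. No label, header or table ties a suffix to a treatment, and none was inferred from order or values. The comparisons of 20a-LNP with PBS, of 20mix-LNP with PBS and of both LNPs with each other, fixed before the data were examined, were therefore not made. The fallback fixed with them was used: pooled values per cell class, and each library's value under its suffix. The sample sheets (2 files) hold index sequences only and were not used.

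Barcodes were kept with at least 200 detected genes and at most 20% mitochondrial UMIs, which removed 1408 of 4638 (200 under the gene minimum, 1300 over the mitochondrial maximum, 92 of them both). Scrublet, run per library, called 23 doublets, which were removed, leaving 3207 cells (755, 1110 and 1342 for suffixes 1, 2 and 3). Cells were clustered with scanpy 1.11.5 (Python 3.11.15, igraph 0.11.9): log counts per 10000, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, with seed 0 and no batch correction. Mitochondrial and ribosomal protein genes and 6 lists (hepatocyte transcripts, haemoglobin, immediate early, heat shock, interferon response and inflammation) were left out of the variable genes. Clusters were named from marker sets fixed before the data were examined. The scoring rule was set after seeing the data. A cluster took the class with the largest share of its markers at 50 CPM or more and at least 2 times the level in all other cells. That share had to cover most of the markers and at least 3 of them, and to lead the next class by 0.25. Clusters whose 10 leading genes held more markers of another class stayed unnamed, as did shallow ones with no marker of their own among those genes. This left 6 of 22 clusters, with 846 cells, unnamed: 25.7%, 26.8% and 26.5% of the kept cells of suffixes 1, 2 and 3.

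UMIs were summed per class and given as counts per 1000000 UMIs of that sum (CPM), with exact Poisson 95% intervals. Ratios between classes have exact intervals conditional on the total count, and shares have exact (Clopper-Pearson) binomial intervals. All intervals cover counting error only: they contain no variation between animals, libraries or cells. No test was run, because cells are not replicates and no library has a known treatment. Ratios between classes were also computed per library, and orders of list sums that did not hold in all 3 libraries are marked. Classes were compared where each library held at least 50 of their cells. Genes named are, by the rule fixed before the data were examined, the 10 per class with the largest ratio of CPM to the highest CPM in another class (at 50 CPM or more) and the 2 to 4 members of each list with the highest CPM; exceptions are marked. The 21 gene lists were fixed at the same time, and 1 list member (Mx2) had no row. Gene positions come from GENCODE release M21 on GRCm38 (mm10), in which all 483 gene identifiers looked up were found.

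The procedure was tested on simulated data. Cells drawn from the 11 class profiles at their own depth all returned to their class (2361 of 2361), a lenient test because the draws have no variation within a class. In a simulation of Kupffer-like over sinusoidal endothelial-like sums, the ratio interval held a true ratio of 2 for 96% of 100 genes, of 0.5 for 96% of 100 genes and of 1 for 95.5% of 3462 genes. The sums were drawn from the Poisson model that the interval assumes, so this checks the calculation and not how the model suits real cells. In a stricter test, the UMIs of each of the 3207 real cells were parted at random in equal expectation, and each part was clustered and named by itself. Of the 2138 cells named in both parts, 95.7% had the same class in both. The share given their class in both parts was 98.2% for NK or ILC1-like, 97.6% for Kupffer-like and plasmacytoid dendritic-like, 72.0% for sinusoidal endothelial-like, 56.3% for conventional dendritic 2-like and 0% for the 22 vascular endothelial-like cells, so the last of these classes are less firmly drawn.

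Alternatives fixed before the data were examined were no cell filter, a stricter filter (500 genes, 10% mitochondrial UMIs), doublets kept, Leiden resolutions 0.5 and 2, all variable genes in the clustering, class sums scaled by TMM (edgeR 4.0.16 in R 4.3.3, with no test), a denominator without ambient, mitochondrial and ribosomal genes, means over cells, and cells thinned to 1000 UMIs. Added after seeing the data were a clustering without the 9 uptake and sterol lists, lists without the fixed cell type markers, and lists without their leading member.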

Results

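The study asks how the stereochemistry of a cholesterol derivative in an LNP affects endocytosis and mRNA delivery. As known of the study, 20a-LNP carries 20α-hydroxycholesterol and 20mix-LNP a mixture with its 20β epimer. The data are droplet transcriptomes of sorted mouse liver non-parenchymal cells from 3 libraries, 1 per treatment (PBS, 20a-LNP and 20mix-LNP). The deposited matrix holds 24111183 UMIs in 4638 barcodes, with 6144949, 8754827 and 9211407 UMIs under barcode suffixes 1, 2 and 3. Which suffix belongs to which treatment is not given in the sources used here, so no effect of either LNP, and no difference between them, is reported. The values describe which cell classes carried transcripts for endocytosis in general, endosomal trafficking and sterol handling. Uptake of these LNPs and mRNA delivery per cell were not measured. After filtering, 3207 cells remained, with a median of 5669 UMIs and 2104 genes per cell. There are no replicates, and all intervals cover counting error only.

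Endothelial, lymphoid and dendritic cells made up most of the named cells. Sinusoidal endothelial-like cells, the fenestrated lining of the liver sinusoids, were 701 of 3207 (21.9%, 95% interval 20.4 to 23.3). NK or ILC1-like cells were 514 (16.0%, 14.8 to 17.3), plasmacytoid dendritic-like cells 296 (9.23%, 8.25 to 10.3) and Kupffer-like cells, the resident liver macrophages, 211 (6.58%, 5.75 to 7.49). Conventional dendritic 2-like cells were 213 (6.64%), but only 38 of them lay in the library of suffix 1, below the minimum of 50 per library for a comparison. The other named classes were T-like (121), monocyte or monocyte-derived macrophage-like (97), conventional dendritic 1-like (72), neutrophil-like (66), B-like (48) and vascular endothelial-like (22). By library, the sinusoidal endothelial-like share was 21.5%, 10.7% and 31.3% for suffixes 1, 2 and 3. The NK or ILC1-like share was 13.8%, 20.7% and 13.4%, the plasmacytoid dendritic-like share 11.1%, 9.55% and 7.90%, and the Kupffer-like share 9.40%, 5.41% and 5.96%. These are shares of the cells left after the flow sort and the cell filter, and how far the sort, the digestion or the tissue shaped them was not tested. The filter removed 37.2%, 34.2% and 21.8% of the barcodes of suffixes 1, 2 and 3. With the stricter filter, shares were 3.65% (Kupffer-like), 24.7% (NK or ILC1-like) and 22.3% (sinusoidal endothelial-like), so the order of the last 2 depends on the filter. The unnamed cells, 26.4% of the kept cells, are in no class share.

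**Figure D1:**
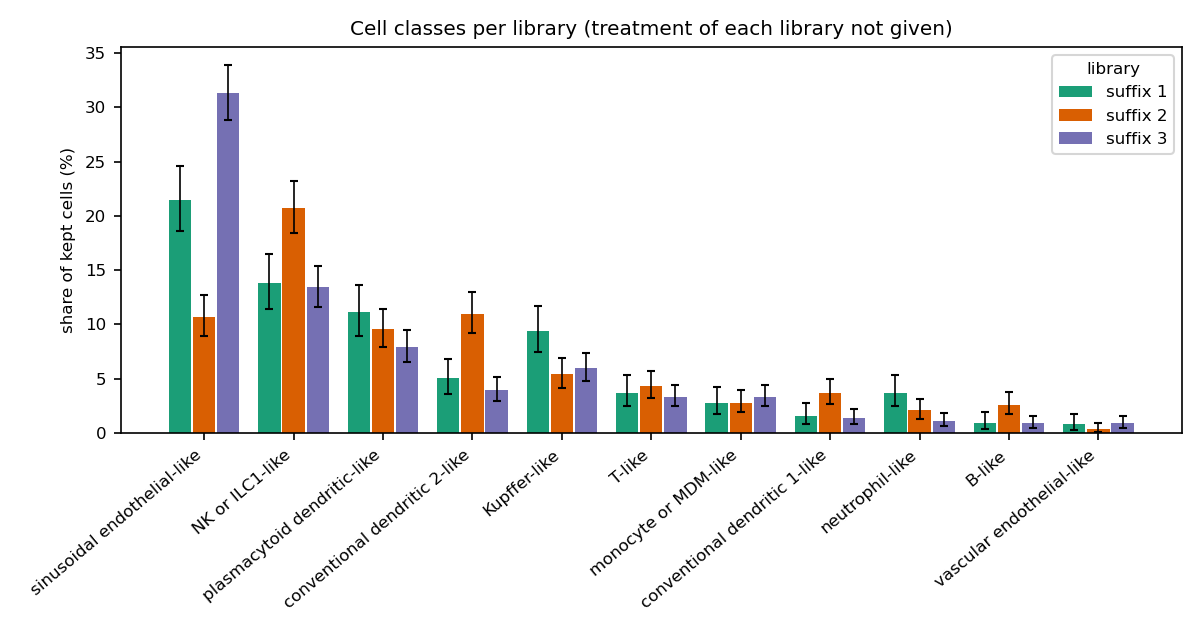
Share of kept cells (%) in each named class, one bar per library (barcode suffixes 1, 2 and 3, treatments not given), with exact binomial 95% intervals of counting error. The sinusoidal endothelial-like share ranges from 10.7% to 31.3% over the libraries.

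The genes that set the classes apart are part of their definition, not findings. For sinusoidal endothelial-like cells the genes with the largest ratio to any other class included Cntfr (78.9 CPM), Rspo3 (147 CPM), Wnt2 (184 CPM) and Col13a1 (415 CPM). For NK or ILC1-like cells they included Klrb1f (211 CPM), Gzmc (680 CPM) and Ncr1 (649 CPM), an activating receptor. The 10 leading genes of cluster 6, with 77 of the NK or ILC1-like cells, were Rgs1, Ifng, Vps37b, Gzmb, Xcl1, Gzmc, Junb, Spry2, Dnajb1 and Neurl3. For plasmacytoid dendritic-like cells the genes with the largest ratio included Cox6a2 (1611 CPM), Klk1 (1274 CPM) and Dntt (266 CPM). For Kupffer-like cells they included Marco (2348 CPM), Cd5l (3909 CPM), Vsig4 (2147 CPM) and Clec4f (4310 CPM). The Kupffer identity list, 9 of whose 12 members are the fixed Kupffer markers, summed to 33597 CPM in Kupffer-like cells and to 296 CPM in sinusoidal endothelial-like cells.

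Genes of clathrin-mediated endocytosis and of caveolae, the flask-shaped membrane pits, were highest in sinusoidal endothelial-like cells among the 4 classes compared. The clathrin list (16 genes) summed to 3042 CPM there (2992 to 3093), 2373 CPM in Kupffer-like, 1446 CPM in plasmacytoid dendritic-like and 1297 CPM in NK or ILC1-like cells, the last 2 in the other order when cells were thinned to 1000 UMIs. The ratio of sinusoidal endothelial-like to Kupffer-like cells was 1.28 (1.22 to 1.34, same direction in 3 of 3 libraries). Under TMM scaling it was 1.03 (0.983 to 1.08), so this order depends on the scaling. Members differed: Dab2, a cargo adaptor for lipoprotein receptors, was at 511 CPM against 209 CPM (ratio 2.44, 2.09 to 2.87), and Cltc, the clathrin heavy chain, at 516 CPM against 384 CPM, whereas Clta, a light chain, was at 295 CPM against 486 CPM. The caveolae list (7 genes) summed to 1607 CPM in sinusoidal endothelial-like cells and 38.2 CPM in Kupffer-like cells, a ratio of 42.1 (29.6 to 62.0, 3 of 3 libraries). Cavin2, a caveolar coat protein (chromosome 1, 51289126 to 51302960), made up most of it at 1316 CPM, with Cav2 at 150 CPM, Cavin1 at 76.0 CPM and Cav1 at 32.7 CPM. Without Cavin2 the ratio was 8.72 (5.97 to 13.3), and with cells thinned to 1000 UMIs it was 64.4 with a wide interval (25.1 to 237).

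**Figure D2:**
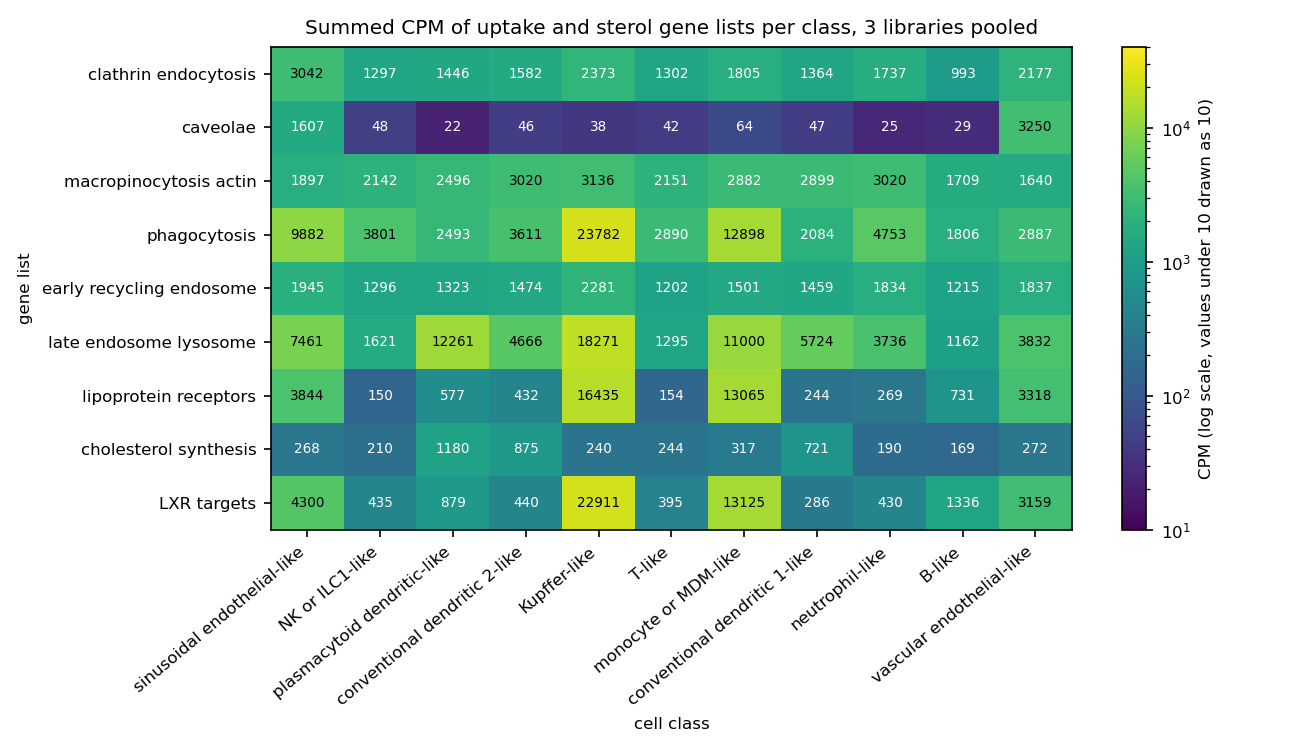
Summed CPM of the 9 uptake and sterol gene lists (rows) in the 11 named classes (columns), 3 libraries pooled, coloured on a log scale with the value written in each cell. Caveolae genes reach 1607 CPM in sinusoidal endothelial-like cells and 3250 CPM in vascular endothelial-like cells.

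Among the 4 classes compared, Kupffer-like cells led in genes of phagocytosis and macropinocytosis. The phagocytosis list (22 genes) summed to 23782 CPM in Kupffer-like cells and 9882 CPM in sinusoidal endothelial-like cells, a ratio of 2.41 (2.37 to 2.45, 3 of 3 libraries). The genes behind these sums differed. C1qa, C1qc, C1qb and Marco led in Kupffer-like cells, and the scavenger and Fc receptors Fcgr2b (2751 CPM), Mrc1 (2421 CPM), Stab1 (1799 CPM) and Stab2 (1393 CPM) in sinusoidal endothelial-like cells. Of the list, 7 genes are also fixed cell type markers, and without them the ratio was 1.07 (1.03 to 1.10). By library it was 1.00, 1.07 and 1.12 for suffixes 1, 2 and 3, so suffix 1 showed almost no difference. NK or ILC1-like cells had 3801 CPM, led by Fcer1g at 2081 CPM, and plasmacytoid dendritic-like cells 2493 CPM. The macropinocytosis and actin list (11 genes) summed to 3136 CPM in Kupffer-like, 2496 CPM in plasmacytoid dendritic-like, 2142 CPM in NK or ILC1-like and 1897 CPM in sinusoidal endothelial-like cells.

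Late endosomal and lysosomal transcripts were highest in Kupffer-like cells among the 4 classes compared, followed by plasmacytoid dendritic-like cells. The list (20 genes) summed to 18271 CPM in Kupffer-like (17979 to 18568), 12261 CPM in plasmacytoid dendritic-like, 7461 CPM in sinusoidal endothelial-like and 1621 CPM in NK or ILC1-like cells. Kupffer-like cells exceeded sinusoidal endothelial-like cells 2.45-fold (2.40 to 2.50, 3 of 3 libraries). Ctsb, which encodes the protease cathepsin B (chromosome 14, 63122462 to 63145923), led in Kupffer-like cells at 5983 CPM. Psap, a precursor of lysosomal activator proteins, led in plasmacytoid dendritic-like cells at 4163 CPM. Ctsl, the gene of cathepsin L, went the other way, at 1816 CPM in sinusoidal endothelial-like and 376 CPM in Kupffer-like cells (4.83-fold, 4.31 to 5.44). Npc1, a lysosomal cholesterol exporter chosen outside the rule for named genes, was at 222 CPM in plasmacytoid dendritic-like, 61.6 CPM in Kupffer-like and 40.3 CPM in sinusoidal endothelial-like cells. The early and recycling endosome list (18 genes) differed less, at 2281 CPM in Kupffer-like and 1945 CPM in sinusoidal endothelial-like cells (1.17-fold, 1.12 to 1.23). Its member Ehd1, a recycling endosome ATPase, was at 528 CPM in Kupffer-like and 38.6 CPM in sinusoidal endothelial-like cells (13.7-fold, 11.5 to 16.4).

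Transcripts for lipoprotein binding were highest in Kupffer-like cells among the 4 classes compared, most of them from 1 gene. The list (10 genes) summed to 16435 CPM there and to 3844 CPM in sinusoidal endothelial-like cells, a ratio of 4.27 (4.18 to 4.37, 3 of 3 libraries). Apoe, which encodes a lipoprotein ligand rather than a receptor (chromosome 7, 19696109 to 19699188), gave 15286 CPM and 2954 CPM of these. Without Apoe the ratio was 1.29 (1.20 to 1.39), at 1.02, 1.51 and 1.40 for suffixes 1, 2 and 3, so suffix 1 showed almost no difference. Lrp1, an endocytic receptor (chromosome 10, 127538161 to 127621148), was at 522 CPM in Kupffer-like cells (474 to 574) and 1.73 CPM in sinusoidal endothelial-like cells. Scarb1, a lipoprotein receptor, was at 159 CPM and 138 CPM, a ratio of 1.15 whose interval (0.945 to 1.39) includes 1 (2 of 3 libraries). Scarb2, a lysosomal membrane receptor, was at 278 CPM and 447 CPM. Among the classes compared, Lrp8 was seen mainly in plasmacytoid dendritic-like cells (117 CPM, against 0.217 CPM in sinusoidal endothelial-like cells).

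Genes of cholesterol synthesis were highest in plasmacytoid dendritic-like cells among the 4 classes compared. The list (20 genes) summed to 1180 CPM there and to 268 CPM in sinusoidal endothelial-like cells, 4.41-fold (4.14 to 4.70, 3 of 3 libraries). It was at 240 CPM in Kupffer-like and 210 CPM in NK or ILC1-like cells, in this order in 2 of 3 libraries. Fdps (152 CPM), Msmo1 (140 CPM), Hmgcs1 (121 CPM) and the sterol sensor Insig1 (111 CPM) led it, and 10 of its members reached 50 CPM in plasmacytoid dendritic-like cells, against 1 in sinusoidal endothelial-like cells, Stard4 (102 CPM), a sterol carrier. Targets of the oxysterol-sensing LXR receptors (14 genes) summed to 22911 CPM in Kupffer-like and 4300 CPM in sinusoidal endothelial-like cells, 5.33-fold (5.22 to 5.44, 3 of 3 libraries). Apoe, Cd5l and Apoc1 made up most of the Kupffer-like sum. Apoe also gave most of the lipoprotein list sum there, Cd5l is also a class marker, and Apoc1 is also in the hepatocyte list. The ratio was 5.66 without Apoe and 4.42 without Cd5l, each left out alone. Without Apoe the sums were 7625 CPM in Kupffer-like and 1347 CPM in sinusoidal endothelial-like cells. Cd5l gave 3909 CPM of the Kupffer-like sum, while the sinusoidal endothelial-like sum without Cd5l was still 4297 CPM. No ratio without all of these was computed, so the 5.33-fold value is not shown to hold for the other targets. Mylip, an LXR target that encodes a ubiquitin ligase, was at 841 CPM in sinusoidal endothelial-like and 80.1 CPM in Kupffer-like cells (10.5-fold, 8.22 to 13.6).

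Stress and response genes differed between the classes. Heat shock genes (10) summed to 8132 CPM in NK or ILC1-like and 7609 CPM in plasmacytoid dendritic-like cells, an order that TMM scaling turned and that 2 of 3 libraries showed, and to 3951 CPM in Kupffer-like and 2259 CPM in sinusoidal endothelial-like cells. Hsp90ab1 and Hspa8 led it in all 4 classes. Immediate early genes (16) summed to 4727 CPM in NK or ILC1-like cells, led by Junb at 1120 CPM, and to 4066 CPM, 1930 CPM and 1392 CPM in plasmacytoid dendritic-like, Kupffer-like and sinusoidal endothelial-like cells. The ratio of Kupffer-like to sinusoidal endothelial-like cells was 0.723, 2.06 and 1.45 for suffixes 1, 2 and 3, and that of NK or ILC1-like to plasmacytoid dendritic-like cells 1.28, 0.988 and 1.32, so both orders turned in 1 library. Enzymatic digestion preceded the sort, so these levels include any response to it. The inflammation list (23 genes) was at 4067 CPM in Kupffer-like cells, with Vcam1 at 2079 CPM, and at 2876 CPM in NK or ILC1-like cells, but Kupffer-like cells were the higher of both in only 2 of 3 libraries (ratios 0.920, 1.58 and 1.71 for suffixes 1, 2 and 3). Plasmacytoid dendritic-like cells had 2622 CPM, led by the chemokine gene Ccl4 (1894 CPM), and lay below NK or ILC1-like cells in 2 of 3 libraries. The interferon response list (25 measured genes) summed to 4715 CPM in plasmacytoid dendritic-like cells, 3805 CPM of it from Bst2, and to 2844 CPM, 2706 CPM and 877 CPM in Kupffer-like, sinusoidal endothelial-like and NK or ILC1-like cells, with Kupffer-like above sinusoidal endothelial-like cells in only 1 of 3 libraries. Unfolded protein response genes (12) summed to 3010 CPM in plasmacytoid dendritic-like, 2713 CPM in Kupffer-like, 1706 CPM in sinusoidal endothelial-like and 1485 CPM in NK or ILC1-like cells, with Hsp90b1 at 1067 CPM in the first. The order of the last 2 of these classes turned when ambient, mitochondrial and ribosomal genes were left out of the denominator. Autophagy genes (14) lay closer together, at 1159 CPM in sinusoidal endothelial-like, 1107 CPM in Kupffer-like, 1062 CPM in plasmacytoid dendritic-like and 881 CPM in NK or ILC1-like cells, and the order of sinusoidal endothelial-like and plasmacytoid dendritic-like cells turned under TMM scaling and the reduced denominator. Kupffer-like cells lay below sinusoidal endothelial-like and above plasmacytoid dendritic-like cells each in 2 of 3 libraries.

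By library, the interferon response list was at 4150, 4965 and 4924 CPM in plasmacytoid dendritic-like cells for suffixes 1, 2 and 3, and at 2527, 3766 and 2445 CPM in Kupffer-like cells. It was at 2540, 3075 and 2671 CPM in sinusoidal endothelial-like cells and at 761, 912 and 905 CPM in NK or ILC1-like cells. Isg15, a ubiquitin-like interferon-induced gene, was at 10.8, 60.7 and 86.6 CPM in plasmacytoid dendritic-like cells but at 106, 66.1 and 70.9 CPM in NK or ILC1-like cells. In plasmacytoid dendritic-like cells it had the widest range over the 3 libraries of all genes ranked by that range. It does not stand for the list there, most of which came from Bst2. Since no treatment can be assigned, these are values of 3 libraries and not of treatments.

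**Figure D3:**
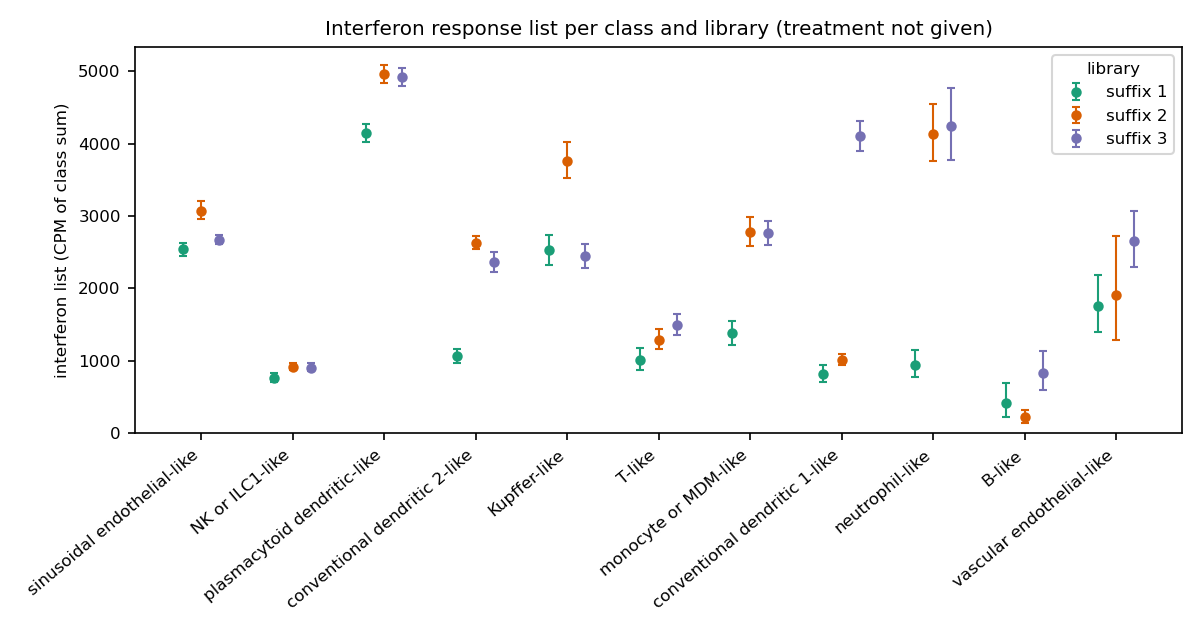
Summed CPM of the interferon response list in each named class, one point per library (barcode suffixes 1, 2 and 3, treatments not given), with exact Poisson 95% intervals of counting error. Plasmacytoid dendritic-like cells lie between 4150 and 4965 CPM in all 3 libraries.

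Within the sinusoidal endothelial-like class, 3 clusters were found. Cluster 9 (415 cells) had 2873 CPM of the periportal list and 1291 CPM of the pericentral list, cluster 11 (213 cells) 1143 CPM and 4228 CPM, and cluster 21 (73 cells) 1238 CPM and 1374 CPM. These lists hold genes that differ along the sinusoid from portal to central vein, and several of them, such as Wnt2, Rspo3, Kit and Ltbp4, lead the clusters and so define them. Over the whole class Fabp4 (1136 CPM) led the pericentral list and Ltbp4 (1078 CPM) the periportal list.

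Transcripts of other cells were measured in the same classes. Hepatocyte transcripts (25 genes) summed to 3232 CPM in Kupffer-like cells, mostly Apoc1 (1945 CPM) and Trf (620 CPM), which macrophages also express, and to 354 CPM, 136 CPM and 116 CPM in sinusoidal endothelial-like, NK or ILC1-like and plasmacytoid dendritic-like cells, the order of the last 2 holding in 2 of 3 libraries. Alb, made by hepatocytes, was at 224 CPM, 92.5 CPM, 28.7 CPM and 11.1 CPM in these 4 classes. Haemoglobin genes (4) were at 121 CPM, 97.3 CPM, 21.1 CPM and 14.5 CPM in the same order, with sinusoidal endothelial-like above NK or ILC1-like and above plasmacytoid dendritic-like cells in 2 of 3 libraries. The sex-linked list was at 295 CPM in sinusoidal endothelial-like cells, led by the Y-linked gene Ddx3y (143 CPM), with 2 Xist UMIs in all kept cells.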

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

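Both tests in this part were chosen before their results were seen. The 1408 barcodes removed by the cell filter were not used in any comparison, and their levels are given as CPM of non-mitochondrial UMIs, where the limit that a count of 0 allows is 1.50 CPM. The hepatocyte list stood at 8773 CPM in the removed barcodes (8644 to 8904), against 433 CPM in the kept cells. Free RNA spread over the droplets would put little of any list gene in any 1 barcode. For Alb, the member examined, 72.5% of its 5572 UMIs lay in the 15 removed barcodes with the most. These values argue against free RNA as the whole source of Alb. How the other members were spread was not examined. Hepatocytes or their fragments among the barcodes are a candidate source: 53 removed barcodes took at least 20% of their non-mitochondrial UMIs from the list, with 21, 22 and 10 of them under suffixes 1, 2 and 3. The flow sort is a step that can remove such cells, and whether they were whole cells stays open. No effect of treatment was tested, since no removed barcode has a known treatment.

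The haemoglobin list reached 199606 CPM in the removed barcodes, above the limit that a count of 0 allows, against 1904 CPM in the kept cells. The plasmacytoid dendritic marker Siglech reached 1726 CPM in the removed barcodes, also above that limit, against 685 CPM in the kept cells. Passing that limit shows only that these transcripts were counted.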

How the results depend on the processing

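The 7 leading list ratios kept their direction under every alternative that gave them a value. They are those of caveolae, clathrin, phagocytosis, lysosome, lipoprotein, cholesterol synthesis and LXR targets, between the classes given below. The early endosome and macropinocytosis lists are not among them. Lists without cell type markers gave values for 2 of the 7, and lists without their leading member for all 7. For sinusoidal endothelial-like over Kupffer-like cells, caveolae ran from 8.72 to 64.4, the latter in thinned cells with an interval of 25.1 to 237. Clathrin ran from 1.03 to 1.41 for the same classes, and its interval under TMM (0.983 to 1.08) includes 1. Values outside the main 95% interval follow, with ratios of Kupffer-like over sinusoidal endothelial-like cells unless another is named. The cause was not tested, except where genes or cells were left out by construction. Without the filter, shares were 27.8% (sinusoidal endothelial-like), 11.2% (NK or ILC1-like) and 6.38% (plasmacytoid dendritic-like), and ratios 2.52 (lysosome), 4.15 (lipoprotein) and 5.20 (LXR). With the stricter filter, shares were 3.65% (Kupffer-like), 24.7% (NK or ILC1-like) and 13.3% (plasmacytoid dendritic-like), and ratios 2.53 (phagocytosis) and 2.54 (lysosome). With doublets kept, the sinusoidal endothelial-like share was 20%, and ratios 2.40 (lysosome), 4.14 (lipoprotein) and 5.19 (LXR). With all variable genes that share was 17.0%, and ratios 2.29 (phagocytosis), 2.34 (lysosome), 4.07 (lipoprotein) and 5.10 (LXR). Phagocytosis was 2.46 at resolution 0.5, 2.33 at resolution 2 and 2.46 in the clustering without the uptake and sterol lists, an alternative chosen after seeing the data.

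Under TMM, ratios were 2.99 (phagocytosis), 3.04 (lysosome), 5.31 (lipoprotein), 6.62 (LXR), 5.36 (cholesterol synthesis, plasmacytoid dendritic-like over sinusoidal endothelial-like) and 1.03 (clathrin, sinusoidal endothelial-like over Kupffer-like). With the reduced denominator, they were 2.56, 2.61, 4.55, 5.67, 5.24 and 1.20 in the same order. As means over cells, ratios were 2.51 (phagocytosis), 4.96 (lipoprotein) and 6.11 (LXR). In thinned cells, which left out 48 of 211 Kupffer-like cells and 2 of 701 sinusoidal endothelial-like cells, they were 2.49 (phagocytosis), 2.64 (lysosome), 4.92 (lipoprotein), 5.74 (LXR), and, for sinusoidal endothelial-like over Kupffer-like cells, 1.41 (clathrin) and 64.4 (caveolae). With lists shortened by choices made after seeing the data, ratios without cell type markers were 1.07 (phagocytosis) and 4.42 (LXR). Without the leading member they were 1.84 (phagocytosis), 1.87 (lysosome), 1.29 (lipoprotein), 5.66 (LXR), 3.94 (cholesterol synthesis, plasmacytoid dendritic-like over sinusoidal endothelial-like) and 8.72 (caveolae, sinusoidal endothelial-like over Kupffer-like).

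Over all 1395 pairs of a list ratio and an alternative, 5 were counted as turned in direction. A turn was counted only where the main interval of the ratio excluded 1. Ratios whose main interval included 1 could change side without being counted. Autophagy in sinusoidal endothelial-like over plasmacytoid dendritic-like cells was 0.898 under TMM and 0.918 with the reduced denominator. Heat shock in NK or ILC1-like over plasmacytoid dendritic-like cells was 0.994 under TMM, unfolded protein response in sinusoidal endothelial-like over NK or ILC1-like cells 0.971 with the reduced denominator, and clathrin in plasmacytoid dendritic-like over NK or ILC1-like cells 0.973 in thinned cells; the cause was not tested. Values recomputed over classes, lists and genes could also leave the main interval without being counted as turned. Leaving aside the settings with shortened lists, their number ran from 23 of 798 at resolution 0.5 to 530 of 789 with the reduced denominator. Some settings gave no value for some results, so these totals differ. Other pseudocounts (5 and 50 CPM) and UMI minimums (10 and 100) apply only to comparisons between treatments and were not run. Leaving out a replicate was not possible with 1 library per treatment. The 48 B-like and 22 vascular endothelial-like cells limit the precision of those classes.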

Other observations

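Among the 6 unnamed clusters, some held gene programmes outside the compared classes and others lay nearest a compared class. Cluster 14, the largest (288 cells, medians of 1692 UMIs and 14.0% mitochondrial UMIs), had 3 of 7 NK or ILC1 markers raised. Cluster 5 (89 cells, median 16.9% mitochondrial UMIs) had 3 of 6 plasmacytoid dendritic markers raised. The shares of the named classes leave these cells out. Cluster 12 (126 cells, with 34, 57 and 35 under suffixes 1, 2 and 3) was led by Ace, Cd300e, Ear2, Fcgr4 and Treml4, genes known from nonclassical monocytes, but only 2 of the fixed monocyte markers were raised. Cluster 20 (22 cells) was led by the cell cycle genes Top2a, Mki67 and Stmn1. Cluster 8 (81 cells) combined haemoglobin genes and Alas2 with the conventional dendritic 1 markers Xcr1 and Naaa. Cluster 7 (240 cells, median 1183 UMIs) was led by Spp1, Clu and haemoglobin genes, with Ttr, Tm4sf4, Cp and Ambp also among its 10 leading genes (Ttr and Ambp are in the hepatocyte list), although 9 sinusoidal endothelial markers were raised in it. These leading genes define the clusters and are no test of what they are.

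The pericentral-type cluster 11 held 18.5% (12.9 to 25.4), 21.0% (14.1 to 29.4) and 37.6% (33.0 to 42.4) of the sinusoidal endothelial-like cells of suffixes 1, 2 and 3, as values of 3 libraries without treatment. In NK or ILC1-like cells, Ccl1 was at 277, 3.24 and 51.9 CPM and Ifng at 604, 243 and 305 CPM over the same libraries. The class joins clusters whose mix differs by library: cluster 6, with Ifng among its leading genes, held 23 of 104, 14 of 230 and 40 of 180 of these cells, and cluster 18 held 12, 48 and 13. In sinusoidal endothelial-like cells Esm1 was at 317, 394 and 124 CPM, while cluster 9, with Esm1 among its leading genes, held 74.7%, 64.7% and 51.7% of the class. How far the cluster mix accounts for these values was not tested. These genes were chosen after their values were seen.

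Of the tests below, those on Alb in Kupffer-like and sinusoidal endothelial-like cells and on the interferon list were chosen only after the result was seen. The interferon list was lowest under suffix 1 in 9 of the 11 named classes by CPM, for example at 1380, 2776 and 2765 CPM in monocyte or monocyte-derived macrophage-like cells, but in 7 of 11 by UMIs per cell; in vascular endothelial-like cells (6 under suffix 1 and 4 under suffix 2) it fell by 5.83 UMIs per cell (1.87 to 9.80, normal approximation, as for the rises that follow). Free RNA alike in every droplet, which would add the same number to each cell, is argued against as the whole cause. From suffix 1 to suffix 2 the list rose by 7.76 UMIs per cell (5.66 to 9.85) in plasmacytoid dendritic-like cells. In NK or ILC1-like cells it rose by 0.622 (0.0691 to 1.17), a ratio of 12.5. Levels under suffix 1 already differed, at 50.1 and 5.5 UMIs per cell, so that ratio does not show a much larger relative rise in plasmacytoid dendritic-like cells. A difference between libraries in handling or sequencing cannot be told apart from treatment, because each treatment has 1 library, and treatment itself stays untested because no suffix is tied to one. The hepatocyte list was highest under suffix 2 in 10 of the 11 classes, and Alb was at 94.4, 494 and 132 CPM in Kupffer-like cells. Under suffix 2, Kupffer-like and sinusoidal endothelial-like cells held 8.09 (5.80 to 11.4) and 4.80 (3.47 to 6.71) times the Alb UMIs per cell of NK or ILC1-like cells. Free RNA alike in every droplet is argued against as the whole source of Alb in these 2 classes. Levels were compared and not rises, so the values do not decide what made suffix 2 the highest. From suffix 1 to suffix 2, Alb went from 0.310 to 1.90 UMIs per cell in Kupffer-like cells. It went from 0.704 to 1.13 in sinusoidal endothelial-like and from 0.0769 to 0.235 in NK or ILC1-like cells. Hepatocyte material taken up by or attached to Kupffer-like or sinusoidal endothelial-like cells may contribute and was not tested. In lymphoid and dendritic classes, the Alb share of 6 hepatocyte genes under suffix 2 was 49.0% (43.6 to 54.4), against 62.7% in the removed barcodes, a difference of -13.7 percentage points that lies between the bounds set beforehand, so a common source of free RNA stays open there.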
